A study of Betula luminifera with 2 samples.

How the data were processed

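Total RNA was extracted with Trizol, and equal amounts from roots, stems and leaves were pooled, per the labels' protocols. The small RNA library was made with the TruSeq Small RNA kit and the degradome library from poly(A) RNA, per the labels' protocols. Each table holds 1 library, so there were no groups of replicates and no test between samples. The aligner, its version and the genome build are not given in the sources used here.

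The small RNA table holds raw reads per listed miRNA, not normalized, per the file headers. Of its 569 entries, 115 had values that were not whole, so the values are expected or estimated counts in which the authors divided reads among entries that share them. Reads were therefore summed over the entries of a sequence, which counts each read once, and the sums were not rounded for display. Entries of the first groups of the file were matched to miRBase, and those of the last group were predicted from hairpins on contigs, per the file headers. Matched entries that lie on no contig carry precursor values from other species. The folding energy index of the file was recomputed from its energy, length and GC content and agreed within rounding for all 569 entries. For 456 placed entries the coordinates, counted from 1, spanned the precursor length. A total of 2 sequences contained an uncalled base, and 1 sequence, AACCTGGCTCTGATACCA, was listed under both miR1511 and miR5139, where each family kept its share of the reads. Families known under paired names (miR156 and miR157, miR165 and miR166, miR170 and miR171, miR482 and miR2118) were merged.

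The degradome table gives, for each alignment of a miRNA to an assembled transcript, a category, a p-value and a score deposited by the authors, and the reads at every position of the transcript. Its columns have no header. From their values they were read as position, reads, reads divided by the number of matches, reads that match 1 place alone, and category, and the definition of the categories is not given in the sources used here. The listed miRNA is written 3′ to 5′ below its site, which was checked against the alignment scores. A pair was counted once per family or candidate and transcript, and a position once per transcript. Reads at a position are those whose 5′ end lies there, counted in full on every contig they match, and shares are of all reads on that transcript. The library total was not used here.

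Named items followed a rule fixed before the data were examined. It takes the 10 families and the 5 candidates with the most reads, the best site of each fixed conserved family, the 10 category 0 sites with the most reads in the authors' deposited table, and 5 candidate sites chosen alike. The rule asked for targets of the textbook class of each family. The transcripts carry no gene names in the tables used, so any listed target was taken instead. The comparisons of target annotation, of textbook target classes and of photosynthesis, secondary wall and translation groups were not run for the same reason.

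Shares have exact binomial intervals at 95%. Matched sequences and candidates were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over length and 5′ base, and folding indices by a permutation test of medians with 100000 resamples. Read levels were compared only as the percentile of a list's median among 10000 random lists. Precursors were refolded with RNAfold 2.7.2 as an alternative. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The Fisher, permutation and random-list procedures were tested on simulated data at the real sizes, while the bootstrap of rank correlations and the intervals of medians were not. With no difference planted, the Fisher test called 5.4% of 505-sequence draws, the permutation test 2% of draws of 392 precursors, and the random lists placed 2.5% of lists outside the central 95%. With planted differences of 50 against 20%, of 0.2 in the index and of 4-fold in reads, they called 100%, 98% and 100%. For the closing section, 14 peptides of textbook target classes were written down from general knowledge and searched in the 3 reading frames of each ungapped site, with 10000 random draws. On simulated sets of 20 sites, this search called 4% of sets with random changes and, with the positions of changes kept, 3%, and it called 100% of sets that encoded the peptides in both versions. Alternatives covered a minimum of 10 reads, weighting by reads, merging of families, contigs or contained sequences, placement on a contig, and stricter degradome categories, p-values or scores.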

Results

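The series surveyed the microRNAs (miRNAs) of Betula luminifera, a birch grown for timber, and the transcripts cleaved at miRNA sites. Seedlings of a single clone, grown in tissue culture to an age of 2 months, gave RNA from root, stem and leaf that was pooled, so no tissue could be compared with another. There was 1 small RNA library and 1 degradome library, which collects the 5′ ends of cleaved polyadenylated transcripts, with no replicates of either. The small RNA table held 607592 reads in 505 distinct mature sequences, and the degradome table held 138872 reads on 64 target transcripts when a read counts on every contig it matches, or 121025 when divided by its matches. Shares of small RNA reads are of the 607592 listed reads, and reads outside the listed miRNAs were not counted. Exact (Clopper-Pearson) binomial intervals at 95% are given below for shares. Because PCR reads without molecular identifiers are not independent molecules, the intervals cover counting error only.

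The question of the small RNA library was which miRNAs these seedlings hold. Of the 505 sequences, 179 matched a miRNA or precursor in miRBase, the public miRNA registry, and fell into 84 families after near-identical family names were merged. The other 326 sequences had no such match and were predicted from hairpins on genome contigs; they are called candidates here. Matched sequences held 598935 reads, 98.6% of the total (interval 98.5 to 98.6%), and candidates 8656.5 reads or 1.42% (1.39 to 1.45%). Every one of the 30 conserved plant families listed before the data were examined was present, so no listed family was missing. The rarest of them were miR827 and miR828 with 1 read each and miR529 with 3 reads. No sequence of miR159, miR168, miR403, miR529, miR535, miR827, miR828, miR858 or miR2111 was placed on a contig. Among all 84 families, 26 had no more than 1 read.

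A single miRNA dominated the listed reads. The miR166 family, which targets class III homeodomain-leucine zipper genes of leaf polarity and vascular development, had 520200 reads, 85.6% of the total (85.5 to 85.7%). Of these, 513486 reads were the sequence TCGGACCAGGCTTCATTCCCC, whose precursor lies on contig_316600, plus strand, positions 710 to 804. The family next in reads was miR156, a regulator of SPL transcription factors and of the juvenile phase, with 18801.5 reads or 3.09% (3.05 to 3.14%). Its main sequence, TTGACAGAAGATAGAGAGCAC, had 16870 reads and came from contig_149866, minus strand, positions 1193 to 1290. The miR894 family followed with 17836 reads, all from CGTTTCACGTCGGGTTCACCA, which the file did not place on any contig. miR1310 had 8782 reads from contig_2804 (plus strand, 414 to 497) and miR2916 had 7450 reads from contig_731 (plus strand, 591 to 681). The hairpins of these last families were 29 and 35 nt long, under the 50 nt that the file header asks for.

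The remaining families of the first 10 were all deeply conserved. miR482, which targets NBS-LRR disease resistance genes, had 7027 reads. miR319, which targets TCP transcription factors of leaf growth, had 4754.5 reads, and miR167, which targets auxin response factors, had 2839.5. miR396, which targets growth-regulating factors, had 1845 reads. miR408, which targets transcripts of copper proteins, had 1736 reads. Together the first 10 families held 97.3% of the reads (97.27 to 97.35%). With the most abundant sequence left out, the share was 82.7%. The plot of reads by family shows the gap between miR166 and the rest.

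**Figure D1:**
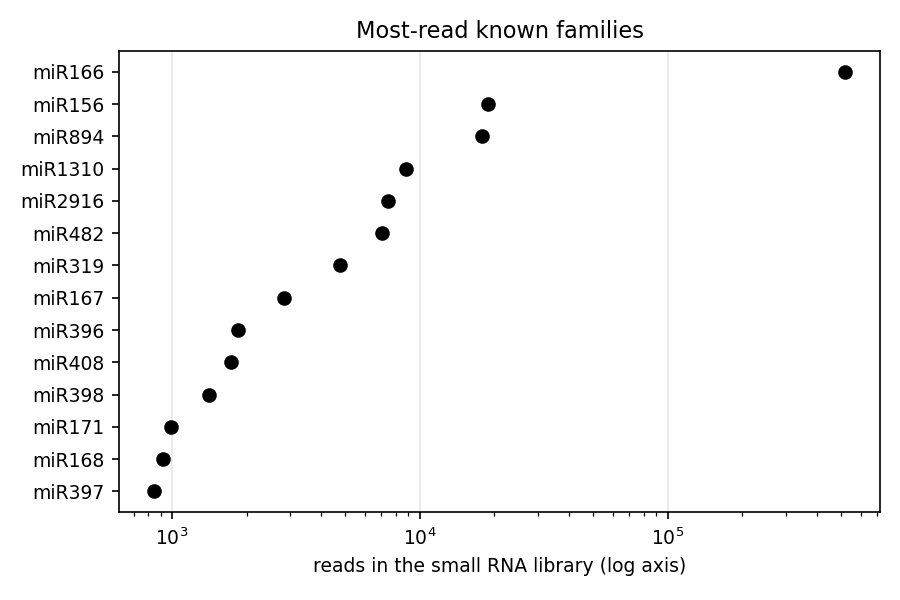
Reads of the 14 most-read families in the single small RNA library, on a log axis, with 1 point per family. miR166 stands at 520200 reads, ahead of miR156 at 18801.5.

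The candidate with the most reads, PC-5p-407_1164 (TCAAAAACTTCTTTTGCCTCT, contig_187275, plus strand, 1105 to 1204), had 1259.5 reads, fewer than miR398 (1408 reads), which came after the first 10 families, and more than miR171 (991.8). It was followed by PC-5p-3808_166 (TATAACAAAGTCTGAATGGTT) with 581 reads and PC-3p-1258_412 (CTGACTGAGGCAAAAGAAGTT) with 531.5. PC-5p-3828_169 (TCTTTTGCCTCTGTCAACATA) had 304 reads and PC-5p-2111_271 (ATCAGCCCAGGACACATGAACAGT) had 283.5. These precursors lay on contig_46726 (plus strand, 495 to 749), contig_325544 (plus strand, 366 to 467, and minus strand, 310 to 413) and contig_141175 (plus strand, 75 to 258). The listed precursors of PC-3p-1258_412 and PC-5p-3828_169 thus overlapped on opposite strands of contig_325544. The other arm of the plus-strand hairpin, PC-5p-34521_16 with 31.5 reads, shared at least 15 nt with PC-5p-407_1164 and with PC-5p-3828_169. Whether these related candidates are separate miRNAs was not tested. The typical sequence of both classes was rare, with a median of 9 reads for matched sequences (interval 5 to 15) and 10 for candidates (9 to 10). Matched sequences spread more widely, with quartiles of 2 and 85 reads against 4 and 16 for candidates. The matched median lay at percentile 23.4 among 10000 random lists of the same size. That percentile changed with the sequences compared. Among sequences with at least 10 reads, and among those placed on a contig, it was at percentile 100.

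Matched sequences and candidates differed in length and in their 5′ base. Of the matched sequences, 82 of 179 (45.8%, 38.4 to 53.4%) were 21 nt long, against 72 of 326 candidates (22.1%, 17.7 to 27.0%), a difference of 23.7 percentage points (two-sided Fisher's exact test, p = 6.3e-08, Benjamini-Hochberg adjusted p = 6.3e-08 over 4 comparisons). Lengths of 24 nt made up 65.0% of the candidates (59.6 to 70.2%) and 9.50% of the matched sequences (5.63 to 14.8%; Fisher's exact p = 1.5e-36, adjusted 6e-36). Uracil was the first base of 103 matched sequences (57.5%, 49.95 to 64.9%) and of 96 candidates (29.4%, 24.6 to 34.7%; Fisher's exact p = 8.6e-10, adjusted 1.1e-09). Adenine opened 55.8% of the candidates and 17.3% of the matched sequences (Fisher's exact p = 7e-18, adjusted 1.4e-17). These tests run across sequences of 1 library, which are not replicates. The matched class was chosen by likeness to miRNAs in miRBase and the candidates by their hairpins. How the classes were made can therefore set part of these differences. Over all 505 sequences, 30.5% were 21 nt long and 39.4% began with uracil. Weighted by reads, these shares were 92.9% and 93.2%. Among candidates, 49.5% of reads were 21 nt and 36.5% were 24 nt long, with uracil first in 42.7% and adenine in 33.7%. The most-read candidate carried this order, since without it the shares were 40.9% and 42.7% for length and 32.9% and 39.4% for the first base.

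**Figure D2:**
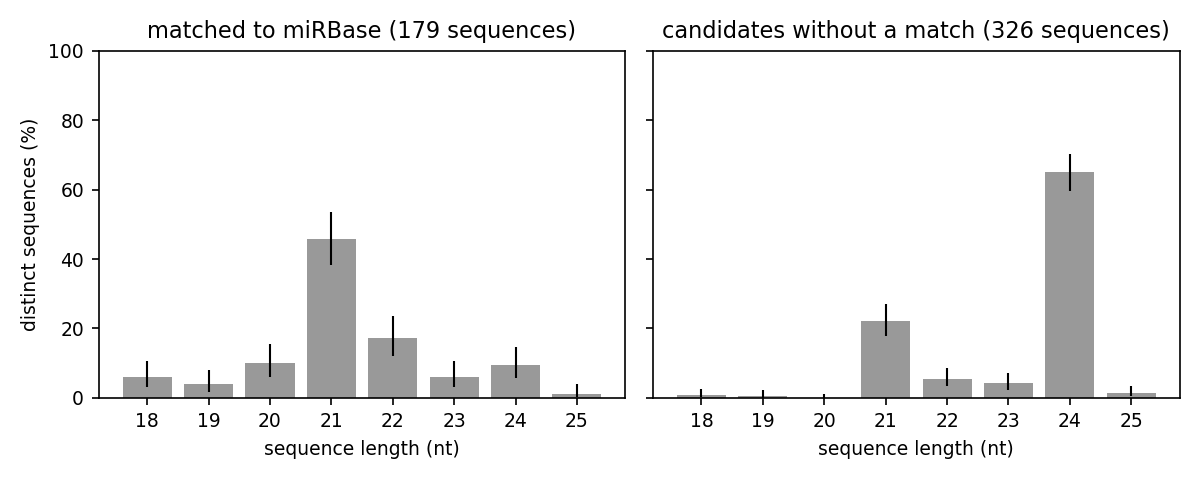
Length in nt (x axis) against the percent of distinct sequences (y axis) for 179 matched sequences and 326 candidates, with exact 95% binomial intervals as bars. The matched sequences peak at 21 nt with 45.8%, and the candidates at 24 nt with 65.0%.

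The listed precursors of candidates had the higher folding index. The minimal folding energy index, the folding energy per length and GC content, had a median of 1.3 over 235 candidate precursors and of 1 over the matched precursors. The difference of -0.3 gave p = 1e-05 in a two-sided permutation test across precursors, the smallest value that 100000 resamples can give. Precursors are not replicates, and some candidate precursors overlap on opposite strands, as on contig_16775, but counted separately. Candidate precursors were also longer (median 154 against 119 nt) and lower in GC (median 35.8% against 44.3%). Many of the matched precursors were sequences of other species. The 52 distinct ones that lay on a genome contig also had a median of 1. No candidate precursor was under 0.9, against 38 matched ones, so the choice of candidates by their hairpins can set part of the difference. Among precursors of at least 0.9 it was -0.2 (permutation p = 0.013). Of the 52 matched precursors on a contig, 3 were under 0.9. Among placed precursors alone the difference was -0.3 (permutation p = 0.0005).

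The degradome asked which transcripts are cleaved at miRNA sites. The authors' deposited table listed 108 alignments of 68 miRNAs, which came to 66 distinct pairs of a family or candidate with a transcript, at 69 distinct cleavage positions. Of these positions, 60 belonged to 23 matched families and 9 to 8 candidates. A listed target was found for 18 of the 30 fixed conserved families, and 14 had a category 0 position in the authors' deposited table. The 12 without a listed target included miR162, miR167, miR169, miR390, miR398 and miR399. The families with the most listed target transcripts were miR156 with 9, miR482 with 7 and miR172, a regulator of AP2 genes, with 5. A category 0 position in the authors' deposited table was found on 2 of these for miR156, 5 for miR482 and 1 for miR172. For miR482 these included CL1452.Contig1 and CL1452.Contig3 of the same assembly cluster. Each had 50 reads at the position, none of which matched 1 contig alone, so they are not separate signals. The miR156 transcripts CL4366.Contig1, CL3355.Contig2 and CL2530.Contig1 were listed only for ptc-MIR156k-p3, a member with 1 small RNA read. Unigene28625 was listed only for tcc-MIR156f-p3, with 3 reads. Both of these members are named for the 3′ arm of the hairpin, and neither is the main miR156 sequence. With contigs of the same assembly cluster merged, and at any category, miR156 kept 9 listed targets, miR482 had 5, and miR172 had 4, as did miR159. The targets carry assembly names only, so which genes they are was not analysed here.

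The deepest cleavage signals belonged to a few families. The position with the most reads was that of miR828, which targets MYB transcription factors, at position 55 of Unigene24455, with 1819 of the 2647 reads on that transcript (68.7%, 66.9 to 70.5%). The matching miRNA itself was listed with 1 read. miR408 had 1717 of 4228 reads (40.6%, 39.1 to 42.1%) at position 2467 of CL468.Contig5. miR858, another regulator of MYB genes, had 1631 of 4398 reads (37.1%, 35.7 to 38.5%) at position 363 of Unigene12428. miR393, which targets auxin receptors, had 356 of 712 reads (50%, 46.3 to 53.7%) at position 1645 of Unigene7232 and 9.64% of 1702 reads (8.27 to 11.1%) at position 1950 of CL986.Contig1. miR482 had 277 of 450 reads (61.6%, 56.9 to 66.1%) at position 91 of Unigene26060 and 211 of 510 reads at position 73 of CL2150.Contig3, both listed for a member with 2 small RNA reads. That member had 0.0285% of the 7027 small RNA reads of the family. miR156 had 144 of 333 reads (43.2%, 37.9 to 48.8%) at position 1762 of CL6199.Contig2, within the site GUGCUCUCUCUCUUCUGUCAA. miR394 had 98 reads at position 540 of Unigene6267, but only 1.03% (0.834 to 1.25%) of the 9550 reads there, with 94 reads at the next highest position. miR171 had 90 of 565 reads (15.9%, 13.0 to 19.2%) at position 1407 of CL3425.Contig1. All of these were of category 0 in the authors' deposited table.

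Other conserved families had fewer reads at their best position. These were miR319 with 84 of 517 reads at position 2229 of CL6050.Contig2, miR159 with 81 of 124 at position 458 of Unigene184, and miR172 with 63 of 498 at position 946 of CL831.Contig13. miR164, a regulator of NAC genes, had 27 of 124 reads at position 601 of Unigene9399. miR160, which targets auxin response factors, had 17 of 70 reads at position 53 of Unigene8556. miR166 had 42 of 2082 reads (2.02%, 1.46 to 2.72%) at position 314 of Unigene12425, where the listed members had 0.0757% of the 520200 small RNA reads of the family. Its main sequence was listed at position 1268 of Unigene8813, with 31 of 303 reads. Signals of miR397 (18 of 315 reads on Unigene7219) and miR396 (10 of 199 on Unigene211) were not the highest on their transcripts. miR395 and miR168 had 1 read each at their positions, on Unigene1531 and Unigene456, which is too few to tell cleavage from background. The miR396 position was listed only for mtr-miR396b-3p, with 9.32% of the small RNA reads of its family. The miR168 position was listed only for mtr-miR168c-3p, with 6.76%.

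**Figure D3:**
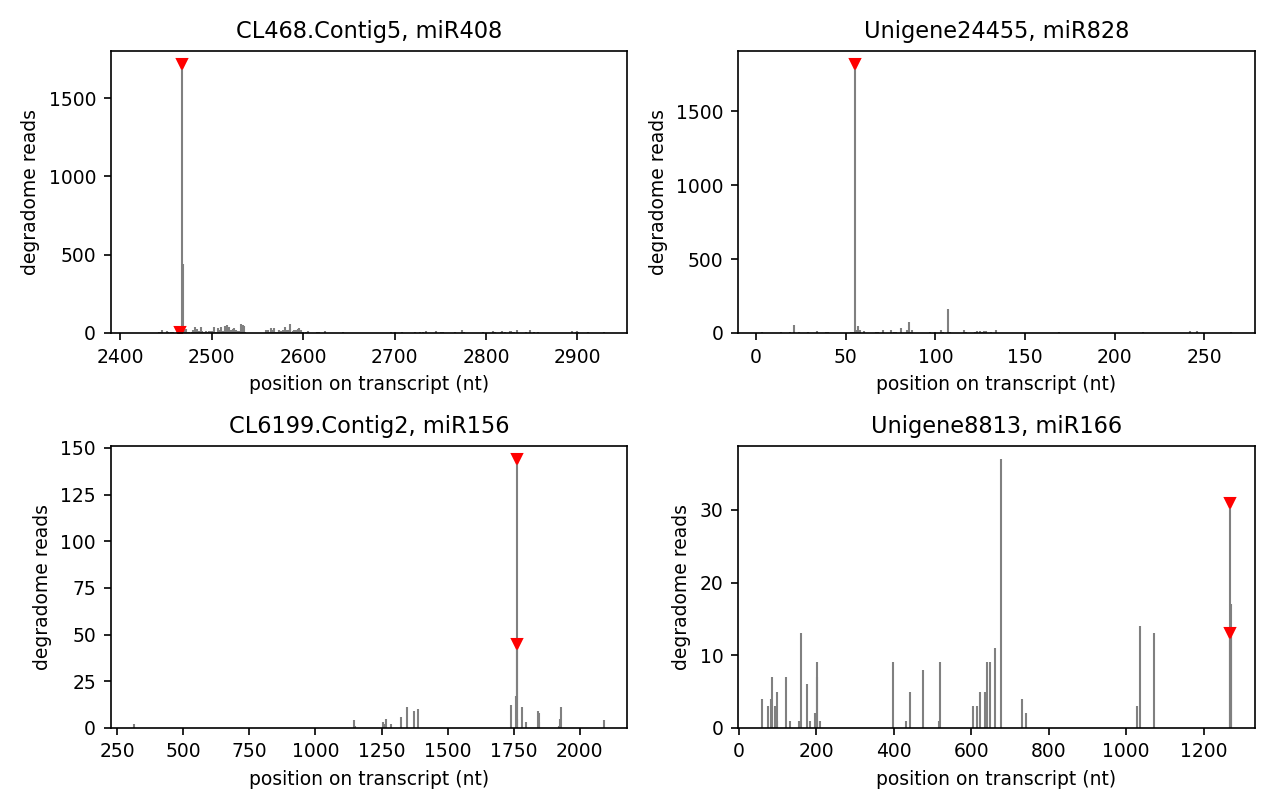
Degradome reads (y axis) by position in nt (x axis) on 4 transcripts, each with its own scale, with red triangles at the cleavage positions of the authors' deposited table. The miR408, miR828 and miR156 positions are the highest on their transcripts with 1717, 1819 and 144 reads, while the miR166 positions on Unigene8813 have 31 and 13 reads beside a peak of 37.

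In the authors' deposited table, 26 of the 69 positions were of category 0 or 1 (37.7%, 26.3 to 50.2%), 24 of category 2, 14 of category 3 and 5 of category 4. Contigs of the same assembly cluster counted separately here, and with them merged the share of category 0 or 1 was 39.1%. Positions of category 0 held a median of 81 reads, and those of category 3 a median of 3. By category in the authors' deposited table, 24 of 60 positions of matched miRNAs (40%, 27.6 to 53.5%) and 2 of 9 of candidates (22.2%, 2.81 to 60.0%) were of category 0 or 1, a difference that did not pass a two-sided Fisher's exact test (p = 0.47). The number of pairs depended on how strictly positions were read. It was 66 in all, 23 at category 0 and 28 at p at most 0.05 in the authors' deposited table.

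Among the candidates, the deepest position was that of PC-5p-5295_120 (TGCGCGAGTTGCGGCGGACCGGGGC), with 31 of 38 reads (81.6%, 65.7 to 92.3%) at position 444 of CL6218.Contig2. PC-5p-1370707_1 had 4 of 4 reads at position 108 of CL5973.Contig2, none of which matched that transcript alone, and 4 of 5079 reads on CL5973.Contig1 of the same cluster. Another candidate, PC-5p-446421_1, was listed at the same position of CL5973.Contig2 and also for CL5973.Contig1. PC-3p-53866_10 had 21 of 3903 reads on CL2665.Contig1 and 21 of 3849 on CL2665.Contig2, contigs of the same assembly cluster, with 90 reads at the highest position of each, and again none of the 21 matched 1 contig alone. PC-3p-1103724_1 had 15 of 411 reads at position 1713 of Unigene5758.

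Among matched sequences, those with a listed target were the more abundant. A target was listed for 56 of 179 matched sequences (31.3%, 24.6 to 38.6%) and for 8 of 326 candidates (2.45%, 1.07 to 4.78%). The 64 sequences with a target had a median of 32 reads, against 9 for the 441 without, at percentile 100 among 10000 random lists of the same size. Within the matched sequences alone, the medians were 47 and 6 reads, at percentile 99.9. The 8 candidates with a target had a median of 7 reads against 10 for the other candidates, at percentile 20.5. This describes 1 library of each kind and has no replicate check.

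**Figure D4:**
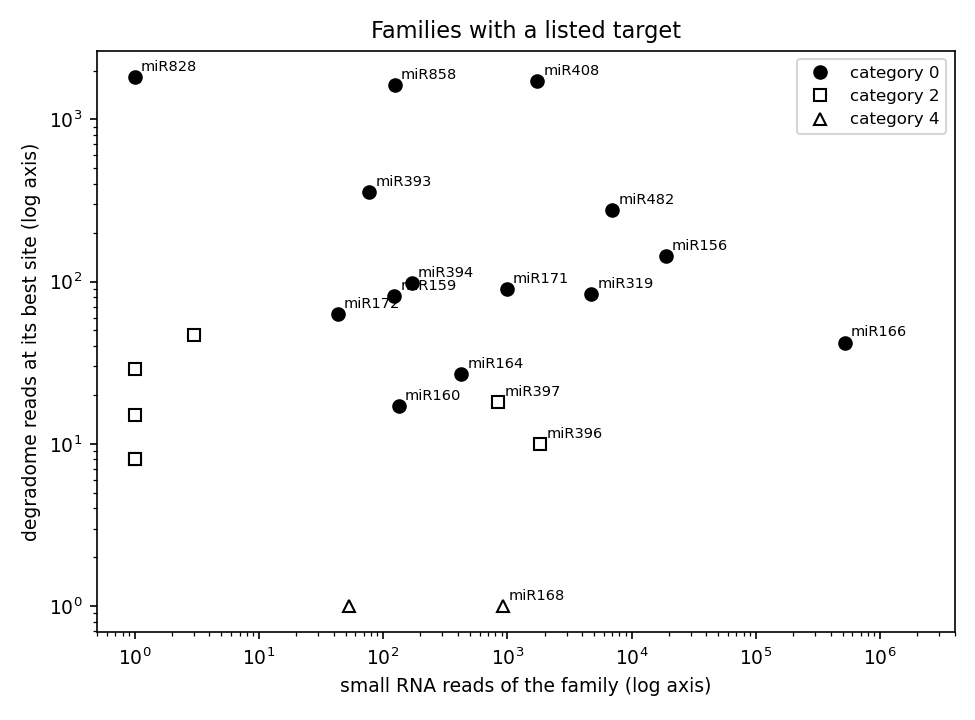
Small RNA reads of each matched family (x axis, log) against degradome reads at its best cleavage position (y axis, log), with 1 point per family for 23 families and symbols by category in the authors' deposited table. Small RNA reads are those of the whole family, not only of the members listed at the position. miR828 lies at 1 and 1819 reads and miR166 at 520200 and 42, and a pair of families shares the point at 1 and 8 reads.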

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

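The tests of 5′ adenine, of base pairing, of miR894 placement and of read ranks below were chosen after the values were seen, while those of shared stretches and of read number among the candidates were set out first. The test of shared stretches at equal numbers was added after the result at full numbers was known, with its outcome set out before it was run. With 1 library of each kind, no biological explanation was tested by a comparison of groups.

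Degradome reads away from the listed cleavage positions were common. On 37 of 60 transcripts with other positions, one more than 1 nt from a listed position held more reads than the listed ones. These reads drew attention on 3 transcripts, where a position more than 1 nt from a listed one held at least 20% of the reads and at least 10 reads. On Unigene8535 position 20 held 369 of 1540 reads, against 4 at the listed miR858 position. On Unigene456 position 447 held 14 of 25 reads, against 1 at the listed miR168 position. On Unigene15020 positions 103 and 148 held 15 and 13 of 61 reads, against 5 at the listed miR858 position.

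Of the distinct candidate sequences, most were 24 nt long, although by reads 49.5% were 21 nt and 36.5% 24 nt long, or 40.9% and 42.7% without the most-read candidate. Of candidates with at least 10 reads, 62.7% (54.8 to 70.0%) were 24 nt long, against 2.35% of matched sequences at that depth. This argues only against sequences under 10 reads as the sole source. Since 10 reads is the candidate median, it does not show that the 24-nt majority holds at higher read numbers. The candidates ranked 1 to 4 by reads were 21 nt long, and the one ranked 5 was 24 nt long. Among 24-nt candidates 72.6% began with adenine, against 23.6% of 21-nt candidates (Fisher's exact p = 3.5e-13, which counts related candidates as separate). A stretch of 15 nt shared with a candidate of another contig was found for 52.4% of the 24-nt and 29.2% of the 21-nt candidates, 23.2 percentage points apart (Fisher's exact p = 0.00064). That test favours the longer and more numerous class. With 72 of the 24-nt candidates drawn, shortened to 21 nt and compared within their own class, the median share was 20.8% (95% of draws, 11.1 to 31.9%). The share was 23.6% for 21-nt candidates, a difference of -2.78 points. Without the draw, the 24-nt share in this comparison was 35.8%. A draw also leaves out relatives of the drawn sequences, so it cannot decide on an origin from repeats. Of the 24-nt candidates 11.8% lay on several contigs, and of the 21-nt ones 11.1%. The 5′ adenine is consistent with an siRNA-like class, and an origin from repeats stays open.

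miR894, miR1310 and miR2916 were among the 5 most-read families. In the precursor structures of the file, a median of 40.9% of the bases of the miR1310 and miR2916 sequences were paired, against a median of 90.5% and a minimum of 66.7% for 23 other entries of the same file groups. The file header sets a minimum for the share of a small RNA in the stem, which can raise the values of the others. These sequences, 2.67% of all listed reads, may be fragments of other RNAs, although no ribosomal or transfer RNA sequence was compared with them. For miR894, 0 entries lay on a contig, so another organism or another RNA as its source cannot be told apart from a missing contig.

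Small RNA reads and degradome reads ranked the families differently, with miR166 and miR828 at the extremes. The contrast of miR166 rests in part on family totals, since the members listed at its best position had 0.0757% of its small RNA reads. Across 23 families, which are not replicates, Spearman's rho between family reads and reads at the best position was 0.236 (bootstrap interval -0.214 to 0.618). With only the reads of the members listed at that position it was 0.273 (-0.197 to 0.638). Between reads elsewhere on the transcript and reads at that position it was 0.311 (-0.128 to 0.660). No interval excludes 0 or a strong relation, so whether miRNA level or transcript depth sets these reads stays open.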

How the results depend on the processing

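Alternatives that concern placement on a contig, the highest entry, hairpins under 50 nt, assembly clusters, score at most 3, precursors with a 21-nt sequence or an index of at least 0.9, matched miRNAs alone and the most-read candidate were chosen after seeing the data. Of 45 alternative values for 14 results, 28 stayed within the interval, within 1.5 times the count, or on the same side of the test, 13 moved and 4 reversed. With at least 10 reads, the number of sequences was 251 and the 21-nt share 37.1%. Weighted by reads, the 21-nt share was 92.9% and the uracil share 93.2%, since miR166 holds most reads. Without the most-read candidate, the read share of 24-nt minus 21-nt candidates went from -13.0 to 1.85 points and that of adenine minus uracil from -9.02 to 6.48. With 1 sequence per matched family and the candidates not merged, the 21-nt and uracil shares were 26.2% and 35.0%, and the uracil share of placed sequences was 34.4%. The share of the first 10 families was 82.7% without the most abundant sequence, 97.7% with the highest entry only, 98.1% for placed sequences and 97.6% without hairpins under 50 nt. The percentile of the matched median went from 23.4 to 100 both with at least 10 reads and for placed sequences. A cut at 10 reads lies near both medians and keeps the upper part of each class, and the upper quartiles were 85 matched and 16 candidate reads. Placement leaves out matched sequences only, and why it moved the percentile was not tested. Pairs fell to 23 at category 0 and 28 at p at most 0.05 in the authors' deposited table, by construction. The differences between matched sequences and candidates in 21-nt share, uracil share and folding index kept their direction and side of the threshold under each alternative run. The differences in 24-nt and adenine shares had no tested alternative. Since reads are divided among entries, counting every entry leaves the read share of families as it is, and every score is at most 4, so neither changes anything. Alternatives on target annotation and textbook classes were not run. No paired analysis was possible because each library stands alone. Depth limits positions with few reads most, and no replicate bounds any value.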

Other observations

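The tests of cleavage registers and of peptides below were chosen after the sites were seen, except the stricter peptide test, whose outcome was set out before it was run.

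Both arms of the hairpin were listed for 33 of 53 matched precursors on contigs, where a miR171 precursor on a pair of contigs counts for each, (62.3%, 47.9 to 75.2%) and for 135 of 235 candidate precursors (57.4%, 50.9 to 63.9%). Where both were listed, the arms differed by a median of 4.02 on the log2 scale in matched precursors (interval 3.21 to 4.73) and of 2.37 in candidates (2.17 to 2.81).

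On 5 transcripts, members of the same family were listed at neighbouring cleavage positions. On CL6199.Contig2 position 1762 had 144 reads and position 1761 had 45, and the miR156 members of these registers had 17036.5 and 976 small RNA reads. On CL3425.Contig1 the order was opposite, with 90 reads at position 1407 and 50 at position 1410, and 363 and 515 small RNA reads of the miR171 members. The register with more small RNA reads had more cleavage reads on 4 of the 5 transcripts, too few to decide whether the more abundant register is cleaved more. CL6199.Contig2 and Unigene25360 among them share the same miR156 members. On CL468.Contig5 the lesser miR408 position had 3 reads, while the unlisted position 2468 had 441.

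A hypothesis was that the sites of conserved families encode peptides of their textbook target classes, for instance ALSLLS of SPL proteins at miR156 sites. Only the longest unbroken run of peptide residues in a reading frame was counted at each site. Over 35 ungapped pairs of 12 families, 136 residues of the fixed peptides were matched in such runs. A whole peptide of 6 residues was encoded by 13 sites. The scoring by partial matches was chosen after the sites were seen. With as many differences placed at random along the complement of the miRNA, a mean of 101 residues was matched (one-sided permutation-type randomisation test, p = 0.0001, the smallest that 10000 draws can give). That comparison is lenient, because target prediction itself limits where mismatches lie and sites of a family share ancestry. With 1 site per family, random placement gave a mean of 46.5 against 63 (same permutation-type test, p = 0.0001). With the differences kept in place as well, 63 residues were matched against a mean of 60.0 (one-sided permutation-type test, p = 0.061). Over all pairs with the differences kept in place it was 136 against 129 (same permutation-type test, p = 0.026). An unbroken run of at least 5 residues was encoded by 17 of the 35 sites and by 15 of the complements of their miRNAs. These had 11 pairs in common, and whole peptides were encoded by 13 and 8. Much of the match can follow from the miRNA sequence, and the hypothesis was not decided.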
